A study of Mus musculus with 9 samples.

How the data were processed

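Gene expression was measured by microarray in mouse RNA labelled as pancreas, in 3 WT and 4 Glis3 mutant samples at E15.5 and in 1 pool of 2 pups per genotype at PND3. Per the labels, E15.5 RNA (100 ng) was labelled in a two-cycle protocol for Affymetrix arrays, and PND3 RNA (500 ng) was purified on Qiagen columns, amplified, and labelled with Cy3 or Cy5 for Agilent arrays. Samples were grouped by the genotype and age in the labels. The labels number the WT samples 1 to 3 and the mutant samples 2 to 5, and nothing in them says that equal numbers share a litter or day. They do not say whether the E15.5 samples came from separate embryos, so p-values measure only the spread between these samples, which may be technical.

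The E15.5 values deposited by the authors are intensities on a linear scale. How the scanner values became that table is not given in the sources used here, and it lists a value for 52.6% to 56.4% of probe sets per array, leaving mostly dim ones empty. The PND3 scanner files hold spot and local background intensities, per the file headers, together with background-subtracted and dye-normalized processed signals. Per the file headers, the scanner's ratio is log10 of Cy5 over Cy3. The other columns used, per the file headers, are spot type and quality flags. The PND3 value table deposited by the authors holds log2 ratios of mutant over WT on both arrays. Scale and direction were found by setting each column against the scanner's ratio of the same array (r = 0.9996 and 0.9997, median 0 for each column). The submitters' processing notes name Agilent Feature Extraction 8.1, whereas the file headers give version 9.1.3.1 and protocol GE2-v5_91_0806.

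Analyses used R 4.3.3 and limma 3.58.1. E15.5 arrays differed in median intensity, so values of probe sets listed on all 7 arrays were quantile-normalized and transformed as log2(value + 16). Fold changes are on that scale, which understates those of dim probe sets. Probe sets under the 40th percentile of mean level were left out, and 12164 were tested with limma (eBayes with a trend, Benjamini-Hochberg adjustment, adjusted p under 0.05). A probe set to gene table for this array was not used here, so probe sets took the place of genes. For the same reason the gene list tests at E15.5, the comparison of E15.5 with PND3, and the mean of a gene's probe sets were not run.

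PND3 background was corrected by normexp with an offset of 50, ratios were normalized by loess within each array with control spots at weight 0, and the array with mutant RNA in Cy3 had its sign turned. The offset draws ratios of dim probes toward 0. Each array held 45018 spots, of which 43379 were not controls. Spots marked as outliers by the scanner software (18 and 26) were left out, and no spot was saturated. Between 72.8% and 76.6% of spots were well above background per channel. Of 41174 probes, 22951 matched a RefSeq symbol through their accession in a table for GRCm38.p6, used for names only, and the others kept the file's name. The brightest probe stood for each gene, among probes well above background in at least 1 genotype on both arrays. Omitting outlier spots can remove a gene's brightest probe, as happened for Slc34a1, which is then represented by a dimmer probe. A gene was counted when its ratio was 2-fold or more in the same direction on both arrays. Where 1 genotype was not well above background on either array, the fold was computed from channel levels after loess and Aquantile normalization. A dim level was raised to the lowest level of any probe well above background in that genotype and array, where it lay lower. That level is not a detection limit, so such folds are estimates and not lower bounds. Scanner signals are means of the processed signals over both arrays, and no probe's signal measures another's amount.

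The 24 gene lists, the comparisons of mutant with WT, the rule for named genes and most alternatives were fixed before the data were examined. Most tests of explanations were chosen later, as said where they are reported. Each list's median was placed among 10000 random lists of the same size drawn from 20 intensity bins. Lists with fewer than 3 measured genes were left out. Named genes were Glis3, 10 fixed endocrine genes, up to 12 genes with the highest and 12 with the lowest ratio among those 2-fold apart on both arrays, and up to 4 members with the largest ratios of each other list. At E15.5 they were the probe sets with the smallest unadjusted p in each direction, 2 per direction. Alternatives changed the normalization, background correction, filter, offset to the log, probe rule, variance model, block and arrays used. Added after the data were examined were 2 treatments of empty E15.5 cells, a rule requiring every probe of a PND3 gene, RefSeq-matched genes alone, PND3 lists without a filter, and 10 further gene lists (kidney nephron, lung, heart and skeletal muscle, brain, oocyte, collecting duct, proximal tubule, thick limb and distal tubule, podocyte and nephron progenitor), whose members were written before their values were looked at, apart from members of fixed lists that recur in the proximal tubule, distal tubule and podocyte lists. The kidney and oocyte lists were chosen because other genes of those tissues had stood out. Members of the kidney nephron list recur in the lists of nephron parts. Both procedures were tested on simulated data. At PND3 all of 67 probes changed 3-fold and all of 66 changed 4-fold were recovered among 16946 probes, none of 67 changed 1.5-fold was counted, and no unchanged probe was counted. These 16946 were bright probes only, and the simulated noise was preset at a low level. The recovery therefore says nothing about dim probes, such as those of Glis3, Ins2 and Sst.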

Results

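Glis3 is a zinc finger transcription factor, and the series asked how pancreatic gene expression differed between mice homozygous for the Glis3zf mutation and wild-type (WT) mice of the C57BL/6 strain. RNA labelled as pancreas was measured at embryonic day 15.5 (E15.5) and on postnatal day 3 (PND3), on 9 arrays in all. At E15.5 there were 3 WT and 4 mutant samples, each on its own 1-colour Affymetrix array, from 100 ng of RNA. At PND3, RNA of 2 mutant pups was pooled, RNA of 2 WT pups was pooled, and both pools were hybridised together on 2 Agilent 2-colour arrays with the dyes exchanged. The PND3 arrays therefore hold 1 pool per genotype measured on a technical pair of arrays, so no p-value is given for that age. The E15.5 table listed an intensity for between 23701 and 25409 of its 45037 probe sets per array, and 20273 probe sets were listed on all 7 arrays. The number of samples limits the precision at E15.5, and 1 pool per genotype limits what PND3 can show.

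The E15.5 comparison asked which transcripts differed between mutant and WT pancreas before birth. The E15.5 table carries probe set identifiers and was not paired with gene names here, so Glis3, the insulin genes and the other endocrine genes could not be read from it by name. None of the 12164 probe sets tested passed limma at an adjusted p of 0.05, and the smallest adjusted p was 0.182. At an unadjusted p under 0.05 limma counted 274 probe sets, against 608 that chance alone would give. That count depended on the WT samples used. It was 965 without WT replicate 1, 233 without WT replicate 2 and 896 without WT replicate 3. With a block for replicate number it was 1145, so the count of 274 does not show a signal below chance. The lowest unadjusted p values belonged to probe sets with lower signal in the mutants. Probe set 1435939_s_at had a log2 level of 10.28 ± 0.41 (SD, n = 3) in WT and 8.66 ± 0.21 (SD, n = 4) in mutant samples. The difference was -1.62 (SE 0.22), or 3.08-fold, with a limma adjusted p of 0.182. Probe set 1435064_a_at stood at 13.02 ± 0.35 (SD, n = 3) in WT and 11.71 ± 0.16 (SD, n = 4) in mutant samples, a difference of -1.31 (SE 0.17) with the same limma adjusted p of 0.182. In the other direction, probe set 1417399_at stood at 9.75 ± 0.12 (SD, n = 3) in WT and 10.38 ± 0.11 (SD, n = 4) in mutant samples, a difference of 0.63 (SE 0.13) with a limma adjusted p of 1. Probe set 1434369_a_at differed by 0.90 (SE 0.23), also with a limma adjusted p of 1. In each of these 4 probe sets the WT and mutant arrays did not overlap, yet none passed the correction.

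**Figure D1:**
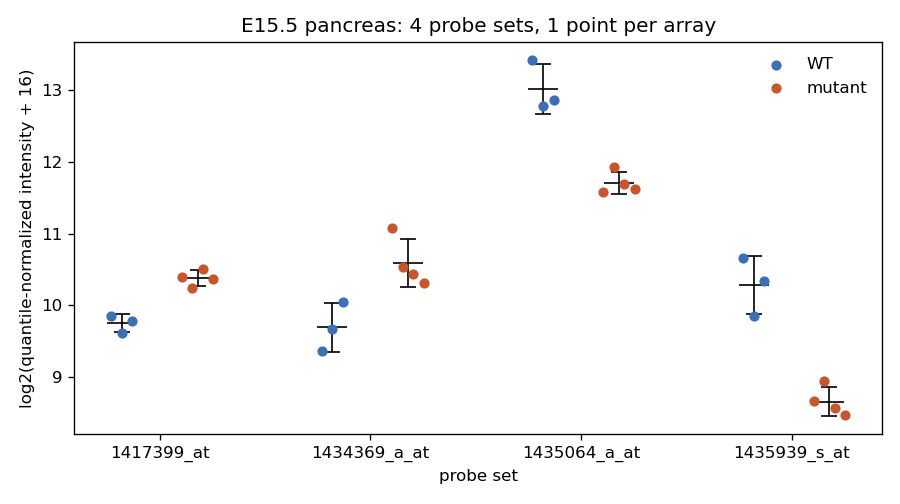
Levels of 4 probe sets on the 7 E15.5 arrays, as log2 of the quantile-normalized intensity plus 16, with 1 point per array, WT in blue and mutant in orange. Horizontal marks are group means and bars are 1 SD. WT and mutant arrays do not overlap in any of the 4, and none of the 4 passed limma's adjusted p of 0.05.

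Across all tested probe sets, 411 (3.38%) had WT and mutant arrays that did not overlap, where chance gives 5.71%. An estimated difference of 2-fold or more was found for 78 probe sets, 58 higher and 20 lower in mutants, and in 22 of them the arrays did not overlap. WT samples varied more among themselves than mutant samples did, with a median SD of 0.27 log2 units against 0.16, and 76.6% of probe sets had the larger SD among WT. Across probe sets, which are not independent replicates, WT arrays correlated with each other at a median r of 0.955, mutant arrays at 0.983, and WT with mutant arrays at 0.969. In data simulated at the pooled spread of each probe set, limma recovered 23.9% of 67 probe sets changed 1.5-fold, 61.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 7.03% of its calls were unchanged probe sets. The simulated noise was independent between probe sets and equal in both genotypes, whereas WT samples here varied more. These shares therefore do not measure what limma would recover from these arrays. Without WT replicate 3 the count was 24 probe sets, 15 higher and 9 lower, and on the intensities without normalization between arrays it was 5, all lower. With a block for replicate number it was 4, 2 higher and 2 lower.

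The PND3 comparison set the mutant pool against the WT pool after birth, with gene names. Both pools were labelled as pancreas, but signals given below argue against pancreas as their main tissue. Of 20922 genes measured, 40 were at least 2-fold apart in the same direction on both arrays, 7 higher and 33 lower in the mutant pool, and 28 of the 40 carried a RefSeq symbol. The lowest ratio among these belonged to Dppa3, although genes dim in the mutant pool, Dppa3 included, cannot be ranked exactly. Dppa3, a maternal factor of the early embryo, had a log2 ratio of -2.74, with the mutant pool well above background on 1 of the 2 arrays. Padi6, an oocyte cytoplasmic protein, stood at -2.46, Zp3, a protein of the zona pellucida, at -1.92, and Gdf9, an oocyte growth factor, at -1.61. Oas1d stood at -2.09, again with the mutant pool well above background on 1 of the 2 arrays. Nlrp14 was an estimated 3.03-fold lower, and it was not well above background in the mutant pool on either array. Khdc3, a component of the oocyte cytoplasm, stood at -1.30 and Amhr2, the receptor of anti-Müllerian hormone, at -1.34. Among those well above background in both pools on both arrays, the scanner software's own ratios were lower still, at -3.31 for Padi6, -3.03 for Zp3 and -2.89 for Khdc3, and at -1.94 for Gdf9 and for Amhr2, so the size of these differences depends on the processing. No scanner ratio is given for Glis3, Dppa3, Oas1d or Nlrp14, where the mutant pool was not well above background on both arrays.

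Other genes at least 2-fold lower on both arrays were the kallikreins Klk1b5 (-1.39) and Klk1b3 (-1.23), the carboxylesterase Ces1g (-1.26) and the anion exchanger Slc26a4, also called pendrin (-1.26). Kallikrein genes are close paralogs, and their probes can bind each other's transcripts. Of the 7 genes at least 2-fold higher, 5 carried a RefSeq symbol. Sprr2f, a small proline-rich protein of epithelia, was highest at 2.03. Ahsg, the plasma protein fetuin-A, stood at 1.64, the Y-linked Eif2s3y at 1.29, the retinaldehyde dehydrogenase Aldh1a1 at 1.17 and Crisp1, a cysteine-rich secretory protein, at 1.10. With the scanner software's ratios these 5 stood at 2.40, 2.24, 1.75, 1.24 and 1.56. With median centring Aldh1a1 fell just under 2-fold and was no longer counted, and the other 39 of the 40 genes were. The array values of each of these genes lay close together, for example 1.98 and 2.08 for Sprr2f and -2.45 and -2.46 for Padi6.

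**Figure D2:**
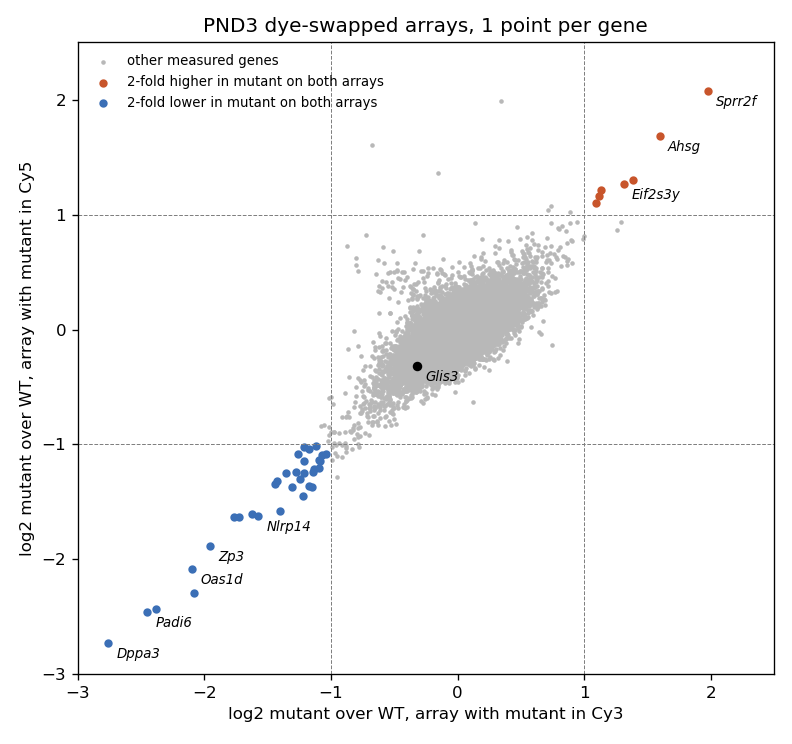
Log2 ratio of mutant over WT for each of 20922 genes at PND3, with the array that carried mutant RNA in Cy3 on the horizontal axis and the array that carried it in Cy5 on the vertical axis. Orange points are the 7 genes at least 2-fold higher and blue points the 33 at least 2-fold lower on both arrays, beyond the dashed lines, and the black point is Glis3 at -0.32. The Glis3 probe was dim, and the background offset draws ratios of dim probes toward 0.

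Glis3 itself had a log2 ratio of -0.32, with -0.32 and -0.31 on the separate arrays. Its probe was well above background in the WT pool on both arrays and in the mutant pool on neither. With the mutant level raised to the lowest level of any probe well above background, the transcript was an estimated 1.16-fold lower in the mutant pool. That estimate is not a lower bound. Whether that probe lies inside the mutated part of the gene is not known here, so its ratio does not check the genotype.

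The labels name pancreas as the tissue of the PND3 arrays, yet hormone and digestive enzyme probes were dim and kidney probes bright in both pools. At a scanner signal of 1000, a level chosen after the values were seen, 0 of 32 hormone and digestive enzyme genes were brighter in both genotypes, against 26 of 30 genes of an added kidney nephron list. Taken in the dimmer genotype, the 32 genes had a median signal of 44.9, against 130.9 for all genes on the array and 7256 for the kidney list. Such dim signals argue against pancreas as the main tissue in either pool, although probes differ in binding. All PND3 ratios, those of the 40 genes and of every list included, are therefore those of these pools. They should not be read as results for pancreas. Of the 8 islet hormone genes, 5 were measured, and none was 2-fold apart on both arrays. Their median log2 ratio was -0.02, at the 51.8th percentile of 10000 random lists of the same size and intensity. Ins2, an insulin gene, stood at -0.01 with scanner signals of 89.1 in the mutant pool and 88.9 in the WT pool, and Sst, encoding somatostatin, at -0.02. Ghrl, encoding ghrelin, stood at 0.48, with 0.49 and 0.46 on the arrays. Ins1, Gcg and Ppy, encoding insulin, glucagon and pancreatic polypeptide, and the beta-cell transcription factor Mafa were not measured, because their probes were not well above background on both arrays in either genotype. The endocrine transcription factors had a median of -0.06 over 16 measured genes, with Neurog3 at 0.07, Pdx1 at 0.07 and Nkx6-1 at -0.08. Beta cell glucose sensing and channel genes had a median of -0.04 over 15, with Slc2a2, a glucose transporter, at -0.19. Secretory granule genes had a median of -0.06 over 18, with the amidating enzyme Pam at -0.68 and the prohormone convertase Pcsk2 at -0.38.

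The exocrine lists also had medians inside the central 95% of random lists, except that with the scanner software's ratios acinar transcription factors had a median of -0.21, at the 2.34th percentile. Acinar digestive enzymes had a median of -0.01 over 20 genes, with the carboxypeptidases Cpb1 at -0.25 and Cpa1 at -0.19. Acinar transcription factors had a median of -0.12 over 6, with Nr5a2 at -0.79 and Gata6 at -0.32. The duct list had a median of 0.01 over 22, with the keratins Krt18 at 0.84, Krt8 at 0.74 and Krt7 at 0.48 and the trefoil factor Tff2 at -0.51. None of the 7 Reg family genes was measured. Hedgehog pathway genes had a median of 0.06 over 16, at the 95.8th percentile, and of 0.14 with the scanner software's ratios, at the 99.0th, with Gas1 at -0.61 and Boc at 0.41. Notch pathway, primary cilium, unfolded protein response and fatty acid lists had medians of -0.02, 0.03, -0.04 and -0.03. Dll1 stood at -0.31, Kif3b at 0.28, Pdia4 at -0.37 and Scd1 at -0.44.

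Of 23 lists measured, 5 had a median outside the central 95% of random lists, where about 1.15 would if the genes of a list varied independently. Genes of 1 tissue can move together between 2 pools, so these counts describe the arrays and test nothing. Adipose tissue genes had the lowest median, -0.81, below all 10000 random lists, and all 9 measured were lower on both arrays. The brown fat uncoupling protein Ucp1 (-1.17) was the only one of them at least 2-fold lower on both arrays, and Cidea, Plin1 and Adipoq stood at -0.95, -0.90 and -0.85. Leukocyte genes had a median of -0.17, at the 0.01th percentile, with 15 of 19 lower on both arrays and Tyrobp at -0.58. On the array with mutant RNA in Cy5 alone they had a median of -0.12, inside the central range. Erythroid genes also had a median of -0.17, at the 0.965th percentile, with Slc4a1 at -0.61. They lay inside the central range with median centring, at the 3.51th percentile, and without the filter on dim probes, at the 19.6th. Cell division genes had a median of 0.08, at the 98.7th percentile, with Top2a at 0.36 and Plk1 at 0.33. With median centring, which moved the median of all genes to -0.11, the list's median was -0.15 and still above the central range, at the 99.1th percentile. On the array with mutant RNA in Cy3 alone it lay inside the range, at the 96.4th percentile. The sex-linked list had a median of 0.64, above all random lists, with Ddx3y at 0.91 and Kdm5d at 0.37, both Y-linked, and Xist, transcribed from the inactive X chromosome, at 0.03. With the scanner software's ratios the list's median was 1.35, with Ddx3y at 1.49 and Kdm5d at 1.22.

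**Figure D3:**
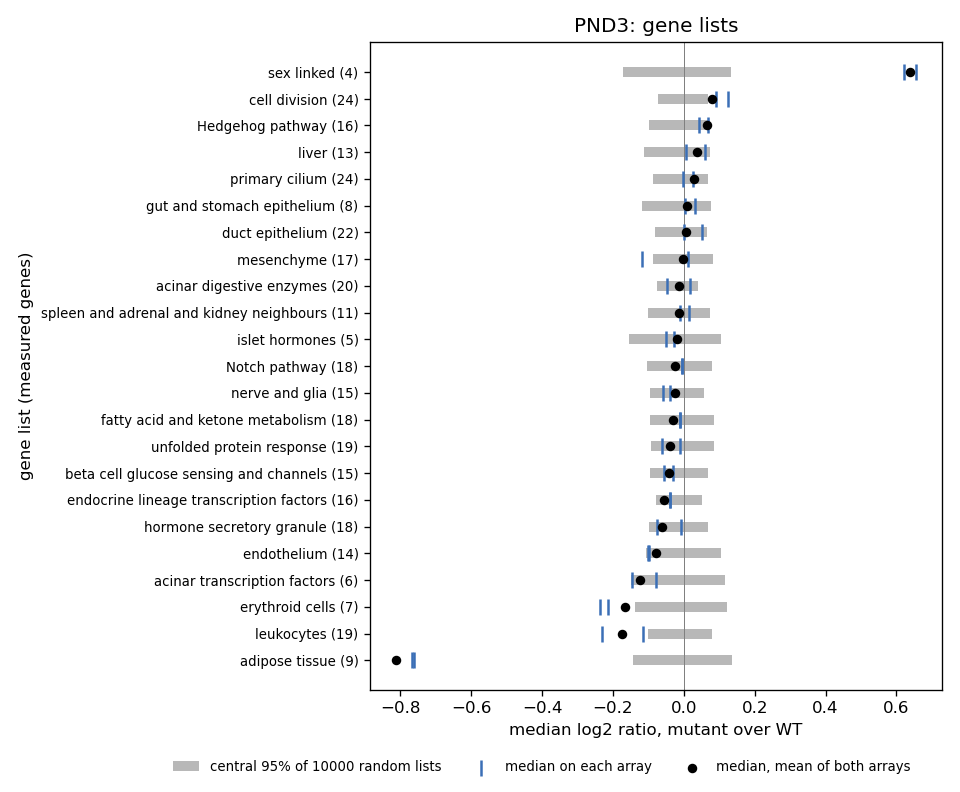
Median log2 ratio of mutant over WT for each of 23 gene lists at PND3, with the number of measured genes in brackets. Black points are the median over both arrays, blue ticks the median on each array and grey bars the central 95% of 10000 random lists of the same size and intensity. Adipose tissue lies at -0.81 and the sex-linked list at 0.64.

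Lists of other cell types and neighbouring organs lay inside that range. Mesenchyme had a median of -0.00 over 17 genes, with the matrix proteins Lum at -0.86 and Col3a1 at -0.52. Endothelium had a median of -0.08 over 14, with Sox17 at -0.36, and nerve and glia a median of -0.02 over 15, with S100b at -0.64. Gut and stomach epithelium had a median of 0.01 over 8, with Lgals4 at 0.59. Liver genes had a median of 0.04 over 13, with Ttr at -0.99, Afp at -0.64 and Alb at 0.55. The spleen, adrenal and kidney list had a median of -0.01 over 11. Slc12a1, a salt transporter of the kidney, gave scanner signals of 19035 in the mutant pool and 21846 in the WT pool. Umod, encoding the kidney protein uromodulin and singled out after its values were seen, gave 47875 and 50921.

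Ratios of the 2 arrays correlated at 0.683 across genes, which are not independent replicates, and 68.7% of genes had the same sign on both. With the scanner software's processed ratios 175 genes, 22 higher and 153 lower, were at least 2-fold apart, and all 40 were among them.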

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

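The treatments of empty E15.5 cells, the every-probe and RefSeq-only rules and the PND3 lists without a filter were chosen after the data were seen. At E15.5 the count of 0 probe sets held under every filter, pseudocount, variance model, median centring and treatment of empty cells. It was 5, all lower, on intensities without normalization between arrays, where the median of all probe sets shifted by -0.25. Leaving out each array in turn gave 0 to 24, with 24 (15 higher, 9 lower) without WT replicate 3 and 0 without any other array. With the replicate block it was 4, 2 higher and 2 lower. The numbers 2 and 3 are shared by both genotypes, and the deviations of same-numbered samples correlated at 0.06 and 0.54, too few pairs to say that the numbers pair the samples. The cause of these shifts was not tested. At PND3 the 40 genes became 175 with the scanner's processed ratios and 175 with the value table, all 40 included. These differ from the ratios used in background correction, dye normalization and offset at once, and the cause was not tested. With median centring 39 of the 40 were kept, without Aldh1a1. The other alternatives gave 28 to 59 genes. The number of lists outside the central range was 4 to 7, against 5. Acinar transcription factors and Hedgehog genes were added by the scanner's ratios and the value table. Erythroid genes were lost with median centring and without the filter, cell division genes without the array with mutant RNA in Cy5, and leukocyte genes without the array with mutant RNA in Cy3. Adipose and sex-linked genes stayed outside the range under every alternative run for the lists. The cell division median was -0.15 with median centring, a scaling that moved the median of all genes to -0.11, and its place among random lists was still high, at the 99.1th percentile, so the sign alone says nothing about that list. No named PND3 gene that was 2-fold apart changed sign. Gene list tests at E15.5, their alternatives, the comparison of E15.5 with PND3 and the mean of a gene's probe sets were not run for lack of gene names. Hormone genes near background limit what the PND3 arrays show for islets.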

Other observations

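The test of labelling strength, the test of Xist, both counts over splits of the E15.5 arrays, the signal level of 1000 with the test of kidney signals, and the test of kidney ratios with median centring were chosen only after the results they bear on were seen. At PND3, collecting duct genes, an added list, had a median log2 ratio of 0.44, above all 10000 random lists, and 8 of 10 were higher in the mutant pool on both arrays. The vasopressin receptor Avpr2 stood at 0.60, Gata3 at 0.54 and the water channels Aqp2 and Aqp4 at 0.49 and 0.48, whereas Hsd11b2 stood at -0.70. None of the list was 2-fold apart on both arrays. Its median stands for these 10 genes alone and not for the whole collecting duct. Hsd11b2, Avpr2, Aqp2, Scnn1b and Fxyd4 are also in the kidney nephron list, so these 2 lists are not separate. The transporters Slc26a4 (-1.26) and Rhbg (-1.12), which are not in the list, went the other way. Other nephron lists had medians of -0.02 (proximal tubule), -0.04 (thick limb and distal tubule), 0.02 (podocyte) and 0.13 (nephron progenitor, 96.7th percentile). The added lung, muscle and brain lists had medians of 0.04, -0.09 and -0.08.

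Singled out after their values were seen, the kallikreins Klk1 (-1.15), Klk1b4 (-1.19) and Klk1b8 (-1.12) were also at least 2-fold lower in the mutant pool on both arrays, as were the ammonium transporter Rhbg (-1.12) and the carbonic anhydrase Car3 (-1.06). Nobox, an oocyte transcription factor, was an estimated 2.27-fold lower, and it was not well above background in the mutant pool on either array.

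Hormone and digestive enzyme probes gave low signals on the PND3 arrays: 0 of 32 such genes exceeded a scanner signal of 1000 in both genotypes, against 26 of 30 kidney nephron genes and 30.2% of all genes, although 78.1% of the 32 were well above background in both genotypes. Weak labelling is argued against by 70.4% of all probes being well above background in both genotypes. That share does not measure whether the RNA was intact, so it cannot exclude degraded RNA. Loess draws bright genes toward 0, so the kidney list's median absolute log2 ratio of 0.15 with it excludes little. With median centring that value was 0.25 and the list's median -0.23, against -0.11 for all genes, which argues against a 2-fold difference in kidney content between the pools. A smaller one stays open, with Kap at -0.88, Miox at -0.82, Slc12a1 at -0.46 and Umod at -0.38 under median centring, as do a difference between parts of the kidney, with the collecting duct list at 0.44 (0.23 with median centring), and differences in other tissues, with adipose and oocyte lists at -0.81 and -0.39. RNA from kidney in both pools may account for a small or a large part of these signals, as a hypothesis. Of the kidney list, 86.7% exceeded the signal of 1000 in both genotypes. The shares were 11.1% for the lung, 10% for the muscle and 20% for the brain list. By nephron part they were 90.9% for proximal tubule, 85.7% for podocyte and 83.3% for thick limb and distal tubule. Collecting duct stood at 80% and nephron progenitor at 37.5%. In the mutant and WT pools, Miox gave signals of 86656 and 122812 and Kap 55103 and 82327. The dim hormone and enzyme signals argue against pancreas as the main tissue in either pool. Other lists were bright too, such as cell division (91.7%) and mesenchyme (78.9%). The share well above background, 100% for the kidney list, does not single it out, since 8 lists fixed before also had 100% and acinar digestive enzymes 83.3%. No kidney list gene is in a list fixed before, how many the pancreas also expresses was not tested, the labels name pancreas and no sort, and probes differ in binding, so these shares do not measure amounts. How much of the RNA came from kidney or another tissue stays open, and no biological explanation was tested.

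Genes known from oocytes had lower ratios in the mutant pool at PND3, and the added oocyte list had a median of -0.39 over 7 genes, below all 10000 random lists, with Gdf9 at -1.61 and Ooep at -1.11. That list was chosen because other oocyte genes had the lowest ratios, from members whose values had not been looked at, so its place is not independent of that pattern. Fewer females in the mutant pool is argued against by Xist, whose probes differed by at most 0.26 log2 units on either array. The Y-linked genes go the other way: Eif2s3y (1.29), Ddx3y (0.91) and Kdm5d (0.37) were all higher in the mutant pool, and the sex-linked list lay above all random lists, so the sex makeup of the pools is not settled. Ovary tissue in the WT pool only cannot be told apart from other sources, because the median of -0.39 lies between the bounds set for it beforehand, -1 and -0.3. All 7 measured list members were well above background in both pools. Nlrp14 and Nobox, which are not in the list, were well above background in the WT pool alone. An effect of genotype stays open and untested, with 1 pool per genotype.

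At E15.5 the real split gave 0 probe sets and the highest count among the other splits of the 7 arrays into 3 and 4 was 1. Every one of the 35 splits gives at least 0, so counting splits (35 of 35) says nothing about chance here. Counting probe sets listed on every array of 1 genotype and on none of the other gave 65, 47 in WT and 18 in mutants. For that count, 16 of the 35 splits gave as many, up to 170, so chance cannot be excluded for it.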
